A study of Mus musculus with 24 samples.

How the data were processed

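Quadriceps muscle of male C57BL/6J mice (a strain that the sample labels write as C56BL/6J) was profiled on Affymetrix mouse genome arrays, a one-colour array on which each gene is read by a set of short probes. After a run-in on the low fat diet, mice ate palm oil diets with 10% (low fat) or 45% (high fat) of the energy as fat, for 3 days or for 28 days, and the labels state random assignment. Each of the 4 groups held 6 mice, each hybridised to its own array, 24 arrays in all. The day 3 mice were 12 weeks old and the day 28 mice 16 weeks old, so time on the diet and age go together. The groups, the days and the mouse numbers were taken from the labels. Low fat mice carried numbers 2010 to 2025 and high fat mice numbers 1751 to 1772, and within each diet the days had separate ranges as well (low fat 2010 to 2019 at day 3 and 2020 to 2025 at day 28, high fat 1767 to 1772 and 1751 to 1758). For 1 array, low fat day 3 replicate 1, the labels' extraction protocol did not name the removal of genomic DNA that it names for the others.

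The deposited table holds 1 intensity per probe set and array, on a linear scale, and per the submitters' processing notes the authors computed these values with GCRMA, a method that corrects the background from probe sequence, normalizes the arrays to one distribution and combines the probes of a set. Its version is not given in the sources used here. The values ran from 0.881 to 20520, and the array medians from 6.56 to 6.90. The spread of the sorted log2 values between arrays reached 0.50, and log2 of the deposited intensity was taken here with no offset and no further normalization. The number of arrays limits the precision, and values of the dim probe sets depend on the background correction, so folds of genes that are dim in one group are on the scale of that correction. Any 2 arrays correlated at 0.978 to 0.995 across all probe sets, and no pair held identical values.

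The table holds 16361 probe sets. Of these, 64 are Affymetrix controls, 14771 are annotated to 1 gene symbol, 589 to several, and 937 are not listed in the annotation used here. Probe sets are named by an Entrez gene number, which equalled the annotated gene for 99.5% of those with 1 symbol. Symbols are those of the platform annotation, and the probe definition behind the probe sets is of a version not stated in the sources used here. A probe set of several genes was named after none of them. The genome build behind the probe sets is not given in the sources used here, so no coordinates are given. Where a gene had more than 1 probe set, the one of highest mean over all arrays was used, which left 14754 genes. A gene was tested when its log2 value exceeded 4 on at least 6 of the 24 arrays, which kept 5793 genes. Among genes fixed for naming, Irs2 did not pass this filter and Srebf1 had no probe set of its own in the annotation used.

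Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) over all 24 arrays, so that the groups shared an estimate of the spread per gene. There were 20 residual degrees of freedom. The 5 comparisons were high fat against low fat at day 3, the same at day 28, the difference between these effects (the interaction), and day 28 against day 3 on each diet. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 5793 genes, and a gene was called at an adjusted p under 0.05. Errors of single genes are given as standard errors (SE) of that fit, and levels as mean ± SD over the 6 arrays of a group. On simulated values with the real means and spreads, in the comparison at day 3 over 5793 genes, the fit recovered 68 of 100 genes changed by 0.5 (log2) and 95 of 100 changed by 1, with 7 unchanged genes called.

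Gene lists were fixed before the data were examined, 35 in all, covering metabolism, fibre types, stress, immunity and markers of other cell types. The 29 lists with at least 5 tested genes were tested with limma's camera at its preset correlation of 0.01, and p-values were adjusted over the lists of a comparison. On simulated values at day 3 over 5793 genes, 3 of 100 unchanged lists had an unadjusted p under 0.05, but these values hold no correlation between genes. On the real values, other splits of the arrays gave a median of 8 called lists at day 3, and 96 of 99 called at least 1, so a called list by itself says little. With the correlation between genes estimated from the data, none of the 29 lists passed in any of the 5 comparisons by camera, with 9, 7, 1, 1 and 2 lists at an unadjusted p under 0.05 in the order above. The third test, fry, called 17, 17, 1, 0 and 0 lists, with 6 and 4 lists at an unadjusted p under 0.05 in the last 2 comparisons. Counts of members called "adjusted over the list alone" use the Benjamini-Hochberg adjustment within the list. The lists not tested for lack of tested genes were cell cycle (4 genes), lymphocyte (1), erythroid (1), nerve and Schwann cell (0), satellite cell (3) and neutrophil and mast cell markers (2).

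The genes named in the text follow a rule also fixed before the data were examined. For each diet comparison these are the 6 called genes with the largest change in each direction, up to 3 called members of smallest p from up to 8 lists, and 12 genes of metabolism and fibre type whether called or not. For the other comparisons these are the 5 called genes of largest change in each direction and up to 2 called members from up to 5 lists. Other members are named only as examples of their list. Hoxd8, Hoxd9, Hoxd10 and Nnt were chosen after their values were seen.

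The alternatives tried were no filter and a stricter filter on dim genes, quantile normalization, a median shift per array, the mean of a gene's probe sets, all annotated probe sets one by one, a trended robust variance, array weights, only the arrays compared, a fold threshold of 1.2, an adjusted p under 0.01, an RNA quality covariate, the replicate number as a block, and each array left out in turn. RNA quality was measured as the mean log2 ratio of the 3 prime to the 5 prime control probe sets of Gapdh and beta-actin. After the data were seen, 4 more were added, namely the mean of the adipocyte markers as a covariate, the mean of the slow fibre genes as a covariate, leaving out 4 arrays, and leaving out the high fat day 3 array of highest adipocyte mean. The 4 arrays had a log2 ratio of the 3 prime to the middle beta-actin control above 2.5, against at most 2.29 on the others. The adipocyte and slow fibre means themselves differ between the diets, which can widen the errors of the diet comparisons. A call lost with either covariate therefore does not by itself show that the covariate accounts for the change.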

Results

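The series measured how the transcriptome of mouse quadriceps, a large thigh muscle of mixed and mostly fast fibres, differed between a high fat and a low fat palm oil diet after 3 days and after 28 days, and so contrasts short with long feeding. Every mouse contributed 1 array, with 6 arrays in each of the 4 groups. The diets were given to mice of separate number ranges, so a difference between 2 sets of animals and a difference between diets cannot be told apart by these samples. The days had separate number ranges within each diet too, so the same holds for the comparisons of day 28 with day 3, in which the mice also differed in age.

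After 3 days, the genes that differed most by diet were those of slow-twitch fibres, which were higher on high fat in all 6 mice than in any low fat mouse for the 6 genes of largest rise. Myh7, the slow myosin heavy chain, had a log2 level of 3.99 ± 2.33 (SD, n = 6) on low fat and 9.59 ± 1.23 (SD, n = 6) on high fat. Of the genes of fatty acid oxidation 14 of 29 were called higher, by smaller steps, and 2 lower, while 6 of 14 genes of fat synthesis and 9 of 15 targets of the glucocorticoid receptor were called lower. These 3 lists had adjusted p = 0.116, 0.315 and 0.0890 with an estimated correlation. Of 5793 genes tested, limma called 861, of which 463 were higher and 398 lower on high fat. Most changes were small, and 53 of the higher and 39 of the lower genes differed by over 2-fold.

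All 12 tested slow fibre genes rose at day 3, over all genes and adjusted over the list alone, with a median log2 change of 3.26. The list was called at an adjusted p = 2.73e-14, and had an adjusted p = 0.0890 with an estimated correlation. Myh7 rose by 5.60 ± 0.92 (log2, SE, adjusted p = 0.000290), Tnnt1 by 5.48 ± 0.79, Myl3 by 5.27 ± 0.95, Tnni1 by 5.25 ± 0.65, Tnnc1 by 4.72 ± 0.70 and Myl2 by 4.01 ± 0.66, all of them slow isoforms of the contractile apparatus. Casq2, the calsequestrin of slow and cardiac muscle, rose by 2.04 ± 0.28. Of 14 fast fibre genes, 2 were higher and 1 lower, with a list adjusted p = 0.916, a median of -0.02 and a test of upward direction. Myh4, the fast IIb myosin heavy chain, had a log2 change of -0.08 ± 0.04 (adjusted p = 0.230), and Myh2, the IIa myosin of fast oxidative fibres, rose by 1.18.

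Markers of some other cell types were higher at day 3 as well. Of 11 endothelial markers, 6 rose and 5 were not called (6 adjusted over the list alone), with a median log2 change of 0.42. That list had an adjusted p = 6.91e-05, and adjusted p = 0.0890 with an estimated correlation. Examples are Esam (0.42 ± 0.08), Egfl7 (0.68 ± 0.14) and Emcn (0.74 ± 0.16), genes of the vessel wall. Of 12 fibroblast and tendon markers, 6 rose and 6 were not called (8 rose adjusted over the list alone), with a median of 0.57 and adjusted p = 0.00106. It had an adjusted p = 0.116 with an estimated correlation. Thbs4 rose by 0.72 ± 0.10, Tnmd by 1.12 ± 0.22 and Scx, a transcription factor of tendon, by 1.10 ± 0.24. Of 8 smooth muscle and pericyte markers, 4 rose, as they did adjusted over the list alone, with a median of 0.40 and adjusted p = 0.00275 (adjusted p = 0.0890 with an estimated correlation). This call was lost with the slow fibre mean as a covariate, at a median of 0.06, adjusted p = 0.315 and no member called. Extracellular matrix genes rose in 7 of 30 cases (9 adjusted over the list alone), among them Col1a2 (0.89), Bgn (0.42) and Sparc (0.57). That list had a median of 0.20 and adjusted p = 0.00604, against adjusted p = 0.490 with an estimated correlation and 0.0885 by fry.

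Fatty acid uptake and oxidation genes rose in 14 of 29 cases at day 3, fell in 2 and were not called in 13 (18 higher and 4 lower adjusted over the list alone), with a median log2 change of 0.27. The list had an adjusted p = 7.81e-08, and adjusted p = 0.116 with an estimated correlation. Slc25a20, the mitochondrial carnitine carrier, rose by 0.58 ± 0.06 (adjusted p = 5.88e-07), Acaa2, a thiolase of beta-oxidation, by 0.80 ± 0.08, and Ech1 by 0.62 ± 0.07. Cpt1b, which makes the acylcarnitines that enter mitochondria, rose by 0.32 ± 0.08 (adjusted p = 0.00966, and 0.0597 when only the arrays compared were fitted). The 2 that fell were Pdk4, which inhibits pyruvate dehydrogenase, with a log2 change of -0.41 ± 0.11 (adjusted p = 0.0167), and Ucp3, a mitochondrial carrier of muscle, with -0.78 ± 0.20 (adjusted p = 0.0103). Neither Pdk4 nor Ucp3 was called with array weights, at adjusted p = 0.0704 and 0.0838.

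Genes of oxidative phosphorylation rose in 17 of 50 cases at day 3, with none lower (27 adjusted over the list alone), and by little, with a median log2 change of 0.14. The list had an adjusted p = 3.74e-11, and adjusted p = 0.116 with an estimated correlation. Examples are Cyc1 (0.23 ± 0.05), Ndufv2 (0.26 ± 0.06) and Ndufa2 (0.24 ± 0.06), parts of complexes III and I, of which Ndufv2 and Ndufa2 lost their call when only the arrays compared were fitted (adjusted p = 0.0534 and 0.0539). Of 17 genes of the tricarboxylic acid cycle, 3 rose (5 adjusted over the list alone), namely Idh2 (1.13), Sdhd (0.26) and Sdhb (0.19), with a median of 0.10, adjusted p = 0.00333 and adjusted p = 0.305 with an estimated correlation (median -0.0162 and adjusted p = 0.885 with the slow fibre mean as a covariate). Of 8 ribosomal protein genes, 3 rose (6 adjusted over the list alone), with a median of 0.18, adjusted p = 0.00553 and adjusted p = 0.298 with an estimated correlation. Ppargc1a, a coactivator of mitochondrial genes, had a log2 change of 0.85 ± 0.35 and was not called (adjusted p = 0.111).

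Glucocorticoid targets fell in 9 of 15 cases at day 3 with none higher (11 lower adjusted over the list alone), with a median log2 change of -0.83. The list had an adjusted p = 4.63e-08, and adjusted p = 0.0890 with an estimated correlation. Klf15, a transcription factor of amino acid breakdown, had a log2 change of -1.21 ± 0.16 (adjusted p = 1.98e-05), Glul, glutamine synthetase, -0.998 ± 0.165, and Cebpd -1.71 ± 0.31. Fkbp5 (-0.89) and Tsc22d3 (-0.65), classical targets of the receptor, fell too. Protein breakdown genes fell in 6 of 11 cases, also adjusted over the list alone, with a median of -0.31, adjusted p = 3.85e-05 and adjusted p = 0.105 with an estimated correlation. Among these, Fbxo32, a muscle ubiquitin ligase known as atrogin-1, had -1.76 ± 0.36, Map1lc3b -0.31 ± 0.06 and the lysosomal protease Ctsl -0.33 ± 0.07. Proteasome genes fell in 7 of 24 cases (8 adjusted over the list alone), with a median of -0.11, adjusted p = 3.53e-05 and adjusted p = 0.116 with an estimated correlation. Examples are Psmd2 (-0.37 ± 0.07), Psmc2 (-0.25 ± 0.05) and Psmd1 (-0.30 ± 0.07). The protein breakdown list (median -0.10, adjusted p = 0.695) and the proteasome list (-0.05, adjusted p = 0.469) were not called with the slow fibre mean as a covariate, nor was any member of either. That covariate parts the diets, and few genes of any kind were called with it.

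Of the 6 largest falls at day 3, Fasn, fatty acid synthase, had a log2 change of -3.26 ± 0.75, Cidec, a lipid droplet protein, -2.65 ± 0.67, Arxes2 -2.57 ± 0.63, Cdo1 -2.48 ± 0.67, Depp1 -2.47 ± 0.61 and Pck1 -2.44 ± 0.61. Of these, Fasn, Cidec, Arxes2, Cdo1 and Pck1 lost their call when only the arrays compared were fitted, at adjusted p of 0.0501 (Fasn) to 0.0709 (Cdo1), and Cdo1 also without the 4 arrays of high beta-actin ratio (0.0565). Fatty acid and triglyceride synthesis genes fell in 6 of 14 cases (7 adjusted over the list alone), with a median of -0.78, adjusted p = 0.00106 and adjusted p = 0.315 with an estimated correlation. That call was lost with the adipocyte marker mean as a covariate (median -0.16, adjusted p = 0.232). Adipocyte markers fell in 3 of 11 cases (Cidec, Pck1 and Retn) and 1, Car3, rose (5 lower and 1 higher adjusted over the list alone). That list had a median of -1.18, adjusted p = 0.00799 and adjusted p = 0.490 with an estimated correlation. It was not called by fry (adjusted p = 0.110). With the slow fibre mean as a covariate it was not called either (adjusted p = 0.0522). Its median was then -1.29, no smaller in size, so that lost call does not show that the slow fibre mean accounts for the fall. The mean of the adipocyte markers was 7.57 ± 1.22 (SD, n = 6) on low fat and 6.31 ± 1.24 (SD, n = 6) on high fat, where replicate 5 stood at 8.67. Scd1, the stearoyl-CoA desaturase, had a log2 change of -1.12 ± 0.50 and was not called (adjusted p = 0.138).

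Of the other lists called at day 3, macrophage markers had 1 of 13 members lower, Cd163 (-0.99), also adjusted over the list alone, with a median of -0.31, adjusted p = 0.0169 and adjusted p = 0.551 with an estimated correlation. Its direction turned with the slow fibre mean as a covariate (median 0.58, adjusted p = 0.000321), and it was not called with the adipocyte marker mean as a covariate (adjusted p = 0.268) or by fry (adjusted p = 0.179). Clock genes had 3 of 11 lower, Nfil3 (-1.29), Rora (-0.48) and Tef (-0.31), with a median of -0.23, adjusted p = 0.0248 and adjusted p = 0.135 with an estimated correlation (5 lower adjusted over the list alone). Oxidative stress genes had 4 lower and 2 higher of 22, led by Gpx3 (-0.93), with a median of -0.17, adjusted p = 0.0169 and adjusted p = 0.135 with an estimated correlation (5 lower and 2 higher adjusted over the list alone). The oxidative stress list lost its call with the adipocyte marker mean (median -0.13, adjusted p = 0.132) and with the slow fibre mean as a covariate (-0.08, adjusted p = 0.303, no member called). Slc2a4, the insulin-responsive glucose transporter, had a log2 change of -0.19 ± 0.07 (adjusted p = 0.0858) and Angptl4, an inhibitor of lipoprotein lipase, -0.37 ± 0.45 (adjusted p = 0.616). Hoxd9, chosen after its value was seen, had the smallest p of this comparison, at 3.30 ± 0.46 on low fat and 6.58 ± 0.49 on high fat (SD, n = 6, adjusted p = 4.07e-09). With the slow fibre mean as a covariate, which itself parts the diets, 18 genes were called at day 3, and with only the arrays compared 507.

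**Figure D1:**
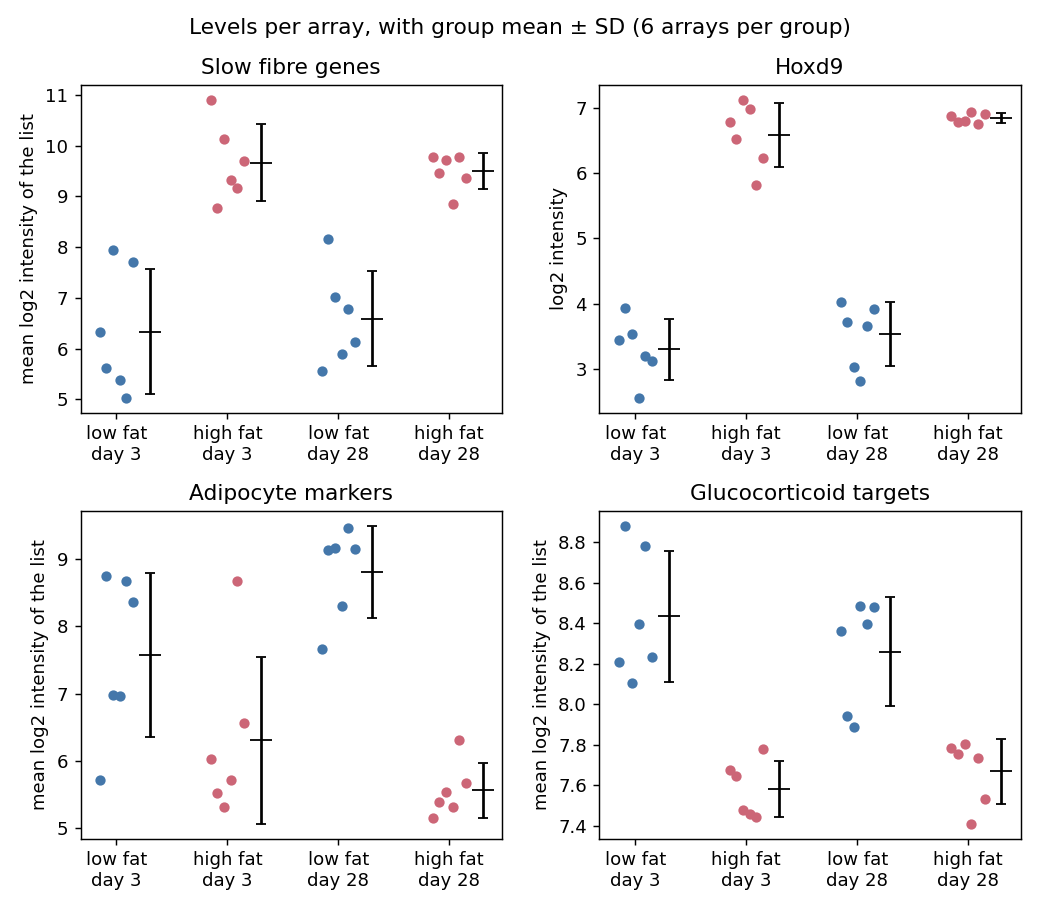
Levels per array (log2 intensity, or the mean log2 intensity of a list) in the 4 groups, 1 dot per mouse, with the group mean ± SD as a black bar. Slow fibre genes and Hoxd9 were higher in all high fat mice than in any low fat mouse, adipocyte markers at day 28 were lower in all high fat mice, and high fat day 3 replicate 5 stood at 8.67 for the adipocyte markers.

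After 28 days, 10 of 12 slow fibre genes and 18 of 29 fatty acid oxidation genes were called higher on high fat, and 10 of 11 adipocyte markers, 12 of 14 fat synthesis genes and 12 of 13 macrophage markers were called lower. Fasn stood at 10.76 ± 0.65 on low fat and 4.78 ± 0.65 on high fat (log2, SD, n = 6), a log2 change of -5.98 ± 0.75 (SE, limma adjusted p = 1.75e-05). Of 5793 genes, 726 were called, 310 higher and 416 lower on high fat. Large falls outnumbered large rises, with 136 genes over 2-fold lower and 36 over 2-fold higher. With quantile normalization the share of higher genes among those called was 52.8%, against 42.7% here.

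Fatty acid and triglyceride synthesis genes fell in 12 of 14 cases at day 28, with none higher (12 lower and 1 higher adjusted over the list alone), and a median log2 change of -1.51. The list had an adjusted p = 3.65e-12, and adjusted p = 0.109 with an estimated correlation. Thrsp, a regulator of lipogenesis, had -3.60 ± 0.42, Acly, which supplies cytosolic acetyl-CoA, -3.65 ± 0.45, the citrate carrier Slc25a1 -4.62 ± 0.61 and Scd1 -3.13 ± 0.50 (adjusted p = 0.000197). Cholesterol synthesis genes had 4 lower and 1 higher of 7, also adjusted over the list alone, with a median of -0.53, adjusted p = 0.0323 and adjusted p = 0.241 with an estimated correlation. With the adipocyte marker mean as a covariate that list had a median of -0.0958 and an upward test (adjusted p = 0.992). With the slow fibre mean it was not called (adjusted p = 0.0891), though its median of -0.59 was no smaller in size. Insig1 (-1.50), Nsdhl (-0.94) and Ebp (-0.76) were among the lower ones, and Fdft1 was higher (0.25).

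Adipocyte markers moved with the synthesis genes. They fell in 10 of 11 cases (10 lower and 1 higher adjusted over the list alone), with a median of -3.49, adjusted p = 1.62e-11 and adjusted p = 0.109 with an estimated correlation. Pck1 had -4.87 ± 0.61, Retn, the hormone resistin, -4.26 ± 0.63, Cidec -4.50 ± 0.67 and Cidea, a gene of brown fat, -5.59 ± 0.85. Ucp1, the uncoupling protein of brown fat, fell as well, with -3.49, and Adipoq, adiponectin, with -2.88. Other genes of large fall were Cdo1 (-5.03 ± 0.67) and Arxes2 (-4.93 ± 0.63). The marker mean was 8.81 ± 0.69 (SD, n = 6) on low fat and 5.56 ± 0.41 (SD, n = 6) on high fat.

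Macrophage markers fell in 12 of 13 cases at day 28, also adjusted over the list alone, with a median log2 change of -1.13. That list had an adjusted p = 3.68e-12, and adjusted p = 0.109 with an estimated correlation. C1qb (-1.55 ± 0.26) and C1qa (-1.51 ± 0.27) encode complement subunits made by macrophages, and Cd163 (-1.13 ± 0.19) their haemoglobin scavenger receptor. The macrophage list was not called with the slow fibre mean as a covariate (median -0.38, adjusted p = 0.0617). Antigen presentation genes fell in 6 of 7 cases (7 adjusted over the list alone), with a median of -0.74, adjusted p = 2.23e-05 and adjusted p = 0.195 with an estimated correlation. H2-D1 had -0.82 ± 0.17, B2m -0.74 ± 0.16 and H2-Eb1 -0.94 ± 0.25. With the adipocyte marker mean as a covariate that list had a median of -0.13 and an upward test (adjusted p = 0.990), H2-D1 had 0.11 and B2m 0.0883, none of them called. Interferon response genes had 2 of 7 lower (3 adjusted over the list alone), Ifi27 (-1.15) and Ifi35 (-0.48), with a median of -0.25, adjusted p = 0.0285 and adjusted p = 0.351 with an estimated correlation, and with that covariate a median of 0.13 (adjusted p = 0.568). It was also not called with the slow fibre mean (adjusted p = 0.0940), without the 4 arrays of high beta-actin ratio (0.0519) or by fry (0.0502).

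Slow fibre genes rose in 10 of 12 cases at day 28 (11 adjusted over the list alone), with a median log2 change of 3.04, adjusted p = 3.65e-12 and adjusted p = 0.109 with an estimated correlation. Myh7 rose by 5.02 ± 0.92 (adjusted p = 0.000759), Tnni1 by 4.87 ± 0.65, Tnnt1 by 4.77 ± 0.79, Myl3 by 4.67 ± 0.95, Tnnc1 by 4.15 ± 0.70 and Myl2 by 3.66 ± 0.66. Atp2a2, the calcium pump of slow fibres, rose by 2.42 ± 0.37 and Casq2 by 1.84 ± 0.28. Csrp3 (0.999) and Ankrd2 (0.23) were not called. Myh4 had a log2 change of 0.03 ± 0.04 (adjusted p = 0.751), of opposite sign with quantile normalization, and 1 of 14 fast fibre genes, Myh2 (0.99), was called. The fast fibre list, with a median of 0.03, was not called by camera (adjusted p = 0.0754) but was called upward by fry (adjusted p = 0.0126). Of 8 smooth muscle and pericyte markers, 3 were higher (4 adjusted over the list alone), with a median of 0.35, adjusted p = 0.00282 and adjusted p = 0.109 with an estimated correlation (median 0.13 and adjusted p = 0.199 with the slow fibre mean as a covariate). Endothelial markers had 1 of 11 higher, Vwf (0.75), with a median of 0.33, adjusted p = 0.0142 and adjusted p = 0.241 with an estimated correlation (6 higher and 1 lower adjusted over the list alone). Fibroblast and tendon markers (4 higher and 2 lower of 12, median 0.38, camera adjusted p = 0.138) and matrix genes (2 higher and 2 lower of 30, median -0.12, camera adjusted p = 0.138 in the downward direction) were not called as lists at day 28. The interaction of the fibroblast and tendon markers was not called either (camera adjusted p = 0.0866, and adjusted p = 0.517 with an estimated correlation).

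Fatty acid uptake and oxidation genes rose in 18 of 29 cases at day 28 and fell in 3 (21 higher and 4 lower adjusted over the list alone), with a median log2 change of 0.28, adjusted p = 2.96e-09 and adjusted p = 0.109 with an estimated correlation. Slc25a20 rose by 0.52 ± 0.06, Acaa2 by 0.73 ± 0.08, Ech1 by 0.57 ± 0.07 and Cpt1b by 0.50 ± 0.08 (adjusted p = 0.000213). The 3 that fell were Angptl4 (-1.62 ± 0.45), Fabp4 (-1.19) and Plin2 (-1.49), of which Fabp4 is an adipocyte marker too. Pdk4 (-0.14 ± 0.11, adjusted p = 0.493) and Ucp3 (-0.45 ± 0.20, adjusted p = 0.154) were not called. Oxidative phosphorylation genes rose in 3 of 50 cases, also adjusted over the list alone, Ndufv1 (0.26 ± 0.06), Ndufb3 (0.19 ± 0.05) and Ndufs1 (0.21 ± 0.06), with a median of 0.07, adjusted p = 0.000261 and adjusted p = 0.351 with an estimated correlation. Tricarboxylic acid cycle genes had 3 higher and 1 lower of 17 (4 and 1 adjusted over the list alone), with Idh2 at 1.57 and Idh3b at -0.90, a median of 0.14, adjusted p = 0.000408 and adjusted p = 0.241 with an estimated correlation. With the slow fibre mean as a covariate neither of these 2 lists was called (adjusted p = 0.557 and 0.491), and oxidative phosphorylation also not with the adipocyte marker mean (adjusted p = 0.0759).

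Glucocorticoid targets fell in 5 of 15 cases at day 28 (8 adjusted over the list alone), with a median log2 change of -0.43, adjusted p = 0.000165 and adjusted p = 0.118 with an estimated correlation. Glul had -1.11 ± 0.17, Angptl4 -1.62 ± 0.45 (adjusted p = 0.0178) and Mt1, a metallothionein, -1.80 ± 0.54 (adjusted p = 0.0292). Angptl4 turned in direction with the adipocyte marker mean as a covariate. Given that mean, the mean of the glucocorticoid targets differed by -0.421 ± 0.226 (log2, SE), against -0.590 ± 0.136 without it. Protein breakdown genes had 3 of 11 lower (4 adjusted over the list alone), with a median of -0.12, adjusted p = 0.0177 and adjusted p = 0.290 with an estimated correlation (median 0.10 and adjusted p = 0.491 with the slow fibre mean as a covariate). That list was also not called with the adipocyte marker mean (median -0.19, adjusted p = 0.203) or without the 4 arrays of high beta-actin ratio (median -0.11, adjusted p = 0.0892). Fbxo32 had -0.07 ± 0.36 (adjusted p = 0.927), with a sign that turned under other settings. Immediate early genes had 1 of 13 higher, Egr1 (1.82), also adjusted over the list alone, with a median of 0.41, adjusted p = 0.0177 and adjusted p = 0.272 with an estimated correlation. With the slow fibre mean as a covariate, glucocorticoid targets (median -0.16, adjusted p = 0.473) and immediate early genes (0.15, adjusted p = 0.455) were not called. Ppargc1a (0.45 ± 0.35, adjusted p = 0.471) and Slc2a4 (-0.08 ± 0.07, adjusted p = 0.568) were not called. Hoxd9 again had the smallest p, at 3.53 ± 0.49 on low fat and 6.84 ± 0.07 on high fat (SD, n = 6, limma adjusted p = 3.38e-09). The day 28 count fell to 35 with the adipocyte marker mean as a covariate, 27 with the slow fibre mean and 403 without the 4 arrays of high 3 prime to middle beta-actin ratio, 3 of which are day 28 arrays. Without single arrays, Mt1 lost its call in 4 fits (low fat day 28 replicate 4, 5 or 6, high fat day 28 replicate 4), Ndufs1 in 2 (low fat day 28 replicate 5, high fat day 28 replicate 6) and Angptl4 in 1 (high fat day 28 replicate 1).

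**Figure D2:**
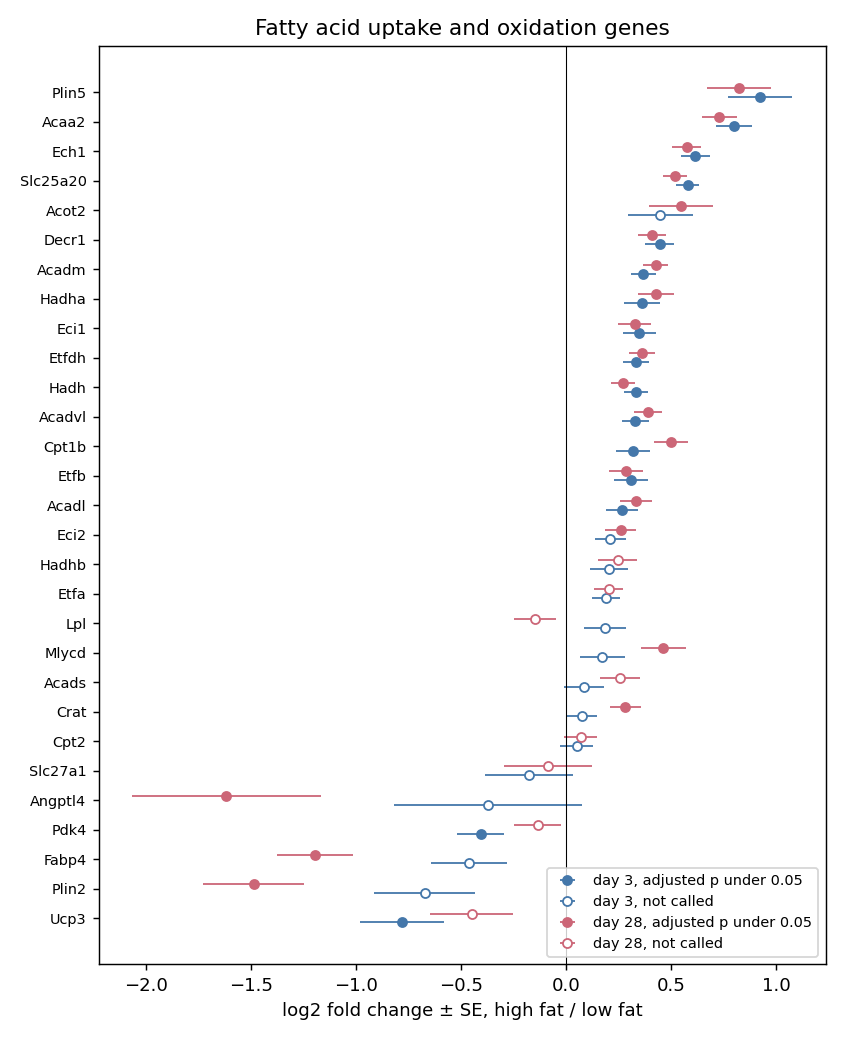
Log2 fold change (high fat over low fat) ± SE of the 29 tested fatty acid uptake and oxidation genes at day 3 (blue) and day 28 (red), filled where the adjusted p was under 0.05. Acaa2, Ech1 and Slc25a20 were higher at both days, while Ucp3 and Pdk4 were lower at day 3 and Angptl4, Fabp4 and Plin2 at day 28.

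The diet differences at the 2 days overlapped and share no arrays, but at both days the diets were given to mice of separate number ranges. A difference between 2 sets of animals could be shared by the days as well, so the overlap does not show that the diet is its source. Of the genes called higher, 131 were called at both days, against 24.8 for independent lists, and of those called lower 103, against 28.6. Across the 5793 genes the log2 changes correlated with Pearson r = 0.646 and Spearman rho = 0.331, where genes are not independent replicates. Of 100 splits of the diets within both days, the real one included, 2 gave as high a Pearson r (highest other 0.648). Of the 1347 genes called at either day, 78.5% had the same sign at both. Slow fibre genes made up the far end of the shared rises, with Myh7 at 5.60 and 5.02, and Fasn, at -3.26 and -5.98, had the largest shared fall.

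**Figure D3:**
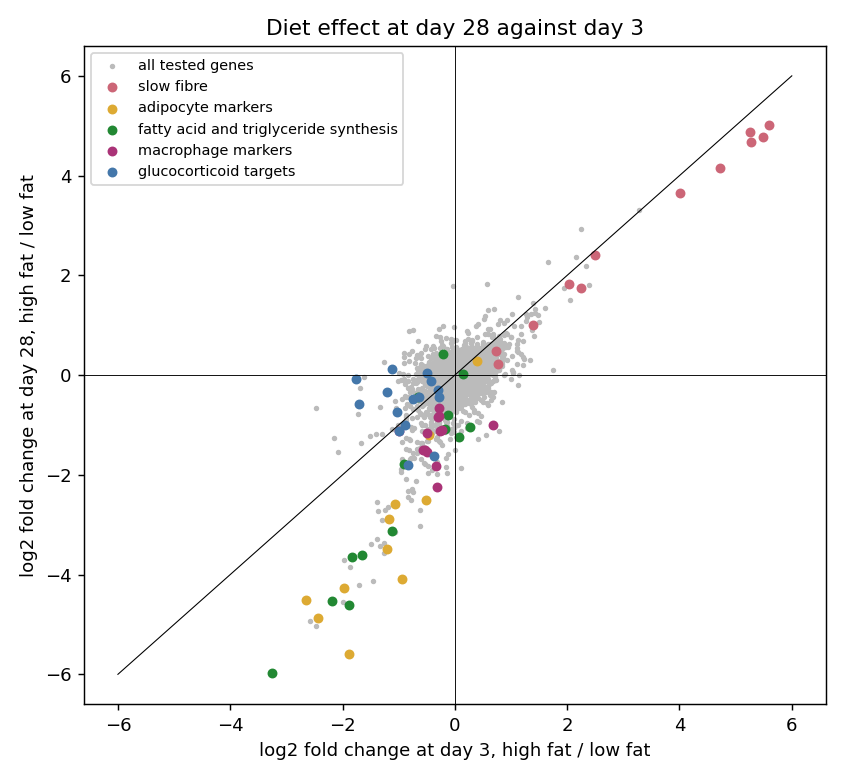
Log2 fold change (high fat over low fat) at day 28 against day 3 for all 5793 tested genes (grey) and the members of 5 lists (coloured), with the line of equal change in black. Slow fibre genes lie at up to 5.60 at day 3 and 5.02 at day 28. They lie below the line, as do the adipocyte and macrophage markers and most fat synthesis genes, though the slow fibre interaction was not called (camera adjusted p = 0.219).

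The interaction tested which diet effects differed between the days. The 80 called genes included 39 whose high fat to low fat change was higher at day 28 and 41 for which it was lower. Slc43a1, an amino acid transporter, was lower on high fat at day 3 (6.46 ± 0.56 on low fat and 4.74 ± 0.46 on high fat, SD, n = 6) and near equal at day 28 (5.26 ± 0.48 and 5.19 ± 0.34), an interaction of 1.64 ± 0.36 (limma adjusted p = 0.0286). Pik3ip1, an inhibitor of phosphoinositide 3-kinase, had 1.26 ± 0.26, Ier3 1.25 ± 0.29, Asb15 1.13 ± 0.25 and Ccrl2 1.04 ± 0.23. In the other direction stood Casp8 (-1.76 ± 0.38), Csad (-1.67 ± 0.41), Gpx8 (-1.51 ± 0.33), Tspo (-1.44 ± 0.29), a protein of the outer mitochondrial membrane, and Pon3 (-1.36 ± 0.22, adjusted p = 0.00873). Sparc, a matrix glycoprotein, had -0.81 ± 0.20 (adjusted p = 0.0411).

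Of the lists, 8 were called for the interaction. Adipocyte markers (median -1.996, adjusted p = 3.66e-05), macrophage markers (-0.86, adjusted p = 3.66e-05), fatty acid and triglyceride synthesis (-1.31, adjusted p = 0.000109), matrix genes (-0.40, adjusted p = 0.000174), oxidative phosphorylation (-0.06, adjusted p = 0.00853) and antigen presentation (-0.57, adjusted p = 0.00853) were lower. Each of these 6 had an adjusted p = 0.517 with an estimated correlation. Clock genes (0.41, adjusted p = 0.00290, and adjusted p = 0.219 with an estimated correlation) and proteasome genes (0.09, adjusted p = 0.00790, and adjusted p = 0.517 with an estimated correlation) were higher. By fry only the clock list was called, the other 7 having adjusted p = 0.133 to 0.184. The synthesis (adjusted p = 0.351), antigen presentation (0.666) and adipocyte lists (0.974) were not called with the adipocyte marker mean as a covariate. The adipocyte list makes up that covariate, so its own lost call is by construction. Sparc was the only member of these lists called over all genes. Adjusted over the list alone, 8 of 11 adipocyte markers, 10 of 14 synthesis genes, 4 of 13 macrophage markers and 2 of 30 matrix genes were lower, and 3 clock genes, 3 proteasome genes and 1 synthesis gene were higher. With the adipocyte marker mean as a covariate limma called 0 genes for the interaction, with 574 at an unadjusted p under 0.05, against 1089 without it. The count was 6 with no filter, 278 with array weights, 176 with the replicate number as a block and 123 with the RNA quality covariate. Without single arrays it was 19 (low fat day 28 replicate 5, high fat day 28 replicate 2), 37 (high fat day 28 replicates 1 and 4), 38 (low fat day 3 replicate 3), 39 (low fat day 3 replicate 6, high fat day 3 replicate 1) and 50 (high fat day 28 replicate 3). Of the 11 genes named, 9 lost their call without at least 1 array and 10, all but Pon3, in at least 1 other planned setting. The share of higher genes was 59.2% with quantile normalization, against 48.8%.

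Between day 3 and day 28, few genes were called on either diet, though 964 on low fat and 834 on high fat had an unadjusted limma p under 0.05. Actc1, cardiac actin, which is also the actin of developing muscle, was called lower on both. On low fat, 20 genes were called, 10 higher and 10 lower at day 28, and on high fat 32, of which 17 were higher and 15 lower. The high fat balance was not stable, with 2 higher and 20 lower when only the arrays compared were fitted (22 genes, 9 of them among the 32) and 1 higher and 8 lower with no filter. Actc1 had a log2 change of -1.06 ± 0.23 on low fat (adjusted p = 0.0485) and -1.65 ± 0.23 on high fat (limma adjusted p = 0.00136). On low fat, Casp8 (1.28 ± 0.27), Rgcc (0.78 ± 0.13), Snhg8 (0.71 ± 0.15), Ebp (0.64 ± 0.14) and the collagen chaperone Serpinh1 (0.63 ± 0.14) rose. Slc43a1 (-1.20 ± 0.25), Nmrk2 (-1.06 ± 0.22), Pik3ip1 (-0.84 ± 0.18) and Tcp11l2 (-0.64 ± 0.11) fell. On high fat, Dnajb1, a heat shock co-chaperone, rose by 2.52 ± 0.54, and Ctf1 (0.59 ± 0.12), Dcaf5 (0.57 ± 0.12), the clock gene Rora (0.52 ± 0.12) and Dglucy (0.52 ± 0.12) rose as well. Mybph (-1.73 ± 0.37), Ecrg4 (-1.65 ± 0.31), the tendon and corneal proteoglycan Kera (-1.33 ± 0.31), Ift27 (-0.92 ± 0.17) and the matrix proteoglycan Bgn (-0.48 ± 0.09) fell.

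Of the lists, 10 were called with time on low fat and 6 on high fat, with Bgn the only member of these called over all genes. On low fat the higher ones were oxidative phosphorylation (median 0.08, adjusted p = 1.41e-05), adipocyte markers (1.01, adjusted p = 0.000393), fatty acid and triglyceride synthesis (0.71, adjusted p = 0.00124), heat shock (0.22, adjusted p = 0.00139), antigen presentation (0.41, adjusted p = 0.00441), macrophage markers (0.38, adjusted p = 0.0330) and interferon response (0.23, adjusted p = 0.0467). Clock genes (-0.14, adjusted p = 0.0185), glucocorticoid targets (-0.19, adjusted p = 0.0269) and immediate early genes (-0.23, adjusted p = 0.0472) were lower. Of these 10, macrophage markers had an adjusted p = 0.597 with an estimated correlation, interferon response an adjusted p = 0.549 with an estimated correlation, and the other 8 lists an adjusted p = 0.534 with an estimated correlation. By fry the 10 had adjusted p = 0.0827 to 0.309. With the adipocyte marker mean as a covariate the synthesis (adjusted p = 0.808), interferon (0.539), adipocyte (0.518), macrophage (0.429) and antigen presentation lists (0.393) were not called, and with the slow fibre mean the glucocorticoid (0.0754) and interferon lists (0.0502). For the adipocyte list, which makes up the adipocyte covariate, the lost call is by construction. Without the 4 arrays of high beta-actin ratio the immediate early (0.1501), heat shock (0.104) and macrophage lists (0.0938) were not called, and the immediate early list also not with no filter (0.109), quantile normalization (0.0786) or the replicate block (0.0536). Adjusted over the list alone, 7 synthesis genes were higher and 1 lower, 3 adipocyte markers, 2 interferon genes and 1 heat shock gene were higher, and 3 clock genes, 2 glucocorticoid targets and 1 immediate early gene were lower.

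On high fat, matrix genes (median -0.31, adjusted p = 1.40e-09, and adjusted p = 0.537 with an estimated correlation), fibroblast and tendon markers (-0.27, adjusted p = 0.000242, and adjusted p = 0.442 with an estimated correlation) and macrophage markers (-0.52, adjusted p = 2.80e-05, and adjusted p = 0.670 with an estimated correlation) were lower with time. So were adipocyte markers (-0.73, adjusted p = 0.00462) and fatty acid and triglyceride synthesis (-0.55, adjusted p = 0.0105), each with an adjusted p = 0.911 with an estimated correlation. Both calls rest on high fat day 3 replicate 5, without which the medians were -0.23 and -0.19, each at adjusted p = 0.205, and 4 lists were called in place of 6. They had adjusted p = 0.587 and 0.466 with the adipocyte marker mean as a covariate, and by fry the 6 lists had adjusted p = 0.0745 to 0.516. For the adipocyte markers, which make up that covariate, the lost call is by construction. Proteasome genes were higher (0.08, adjusted p = 0.00175, and adjusted p = 0.602 with an estimated correlation). Adjusted over the list alone, 9 matrix genes and 1 tendon marker were lower. The low fat count was 0 when its 12 arrays alone were fitted, with 862 genes at an unadjusted p under 0.05 in limma, and 2 without the 4 arrays of high beta-actin ratio. Without single arrays it was 0 in limma for low fat day 3 replicate 6, low fat day 28 replicate 2 and low fat day 28 replicate 5 (847, 905 and 709 genes at an unadjusted p under 0.05), 3 to 13 for low fat day 3 replicates 1, 3 and 4, low fat day 28 replicates 4 and 6, high fat day 3 replicates 1, 2, 3 and 6 and high fat day 28 replicates 2, 3, 4 and 5, and 37, 47 and 59 for low fat day 3 replicate 2, low fat day 28 replicate 1 and high fat day 3 replicate 5. The high fat count was 3 without high fat day 28 replicate 1, 51 without high fat day 3 replicate 2, and 7 to 20 without high fat day 3 replicate 1, 4, 5 or 6, high fat day 28 replicate 2, 3, 4 or 5, low fat day 3 replicate 1, 3, 4 or 6, or low fat day 28 replicate 1, 2 or 3. All 10 genes named on low fat and 10 of the 11 named on high fat, all but Actc1, lost their call without at least 1 array.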

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

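All tests of explanations for the 3 patterns below were chosen after the result was seen, except that of RNA quality, and the counts over other splits of the arrays were fixed in advance.

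Slow fibre genes and Hoxd8, Hoxd9, Hoxd10 and Nnt were higher on high fat at both days, the Hoxd and Nnt mean by 2.29 ± 0.170 (log2, SE) at day 3 and 2.33 ± 0.170 at day 28. Given the slow fibre mean, that mean still differed by 2.09 ± 0.303 and 2.16 ± 0.277, and within the 4 groups the 2 means were weakly related over 24 arrays (r = 0.184, permutation p = 0.458, rho = 0.14, permutation p = 0.566, r = 0.154 without the 2 farthest, adjusted p = 0.458 and 0.566 over 4 relations). By themselves these values go against a larger share of slow muscle as the source of all of these genes. The test cannot decide this, because the Hoxd genes and Nnt were chosen after their diet difference was seen. Hoxd10 on low fat (1.79 and 1.97) also lay near the floor. The slow fibre mean did not overlap between the diets either, at most 8.16 on low fat and at least 8.78 on high fat. A diet effect that builds up mainly after day 3 is argued against, since the day 3 difference exceeded 50% of the day 28 difference by 1.88 ± 0.569 for the slow fibre mean and by 1.12 ± 0.190 for the Hoxd and Nnt mean, though this bound replaced, with all values seen, a first test of the slow fibre difference at day 28 minus that at day 3, which left the question open (-0.429 ± 0.719). A difference between 2 sets of animals cannot be told apart from a diet effect that is largely there by day 3, since 0 ranges of mouse numbers held mice of both diets, although the labels state random assignment. As background, an Nnt deletion is known in the C57BL/6J strain, but no genotype was used here.

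Adipocyte marker and fatty acid synthesis genes were lower on high fat, the mean of the synthesis genes by -2.25 ± 0.334 at day 28. Given the adipocyte marker mean, the difference was -0.381 ± 0.177, so that 83.0% of the full difference went with the marker mean, and the rest was beyond 2 SE and by itself against a smaller share of fat tissue as the whole source. After this value was seen, a correction for error in the marker mean was added, because noise in a covariate leaves part of a difference behind. With the reliability of the marker mean at 0.980 the difference was -0.342 ± 0.180, within 2 SE, so fat share and a diet effect within the tissue cannot be told apart, and this reading rests on the later correction (both means were related within groups, r = 0.950, rho = 0.932, permutation p of 1e-05 each, the smallest that 100000 permutations can give, adjusted p = 4e-05, r = 0.898 without the 2 farthest arrays). A difference in RNA quality, as read by the 3 prime to 5 prime ratio, is argued against by -2.21 ± 0.343 for the synthesis genes and -3.20 ± 0.568 for the markers with that covariate. The test does not cover the 3 prime to middle beta-actin ratio. The 4 arrays on which that ratio was high had the lowest 3 prime to 5 prime ratios of beta-actin (-0.189 to -0.0367).

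Pdk4 and Ucp3 were lower on high fat at day 3, their mean by -0.594 ± 0.149, while 14 of the 29 fatty acid oxidation genes were called higher. A difference in glucocorticoid tone may account for it, as a hypothesis, since the difference was 0.122 ± 0.170 given the glucocorticoid target mean and both means were related within groups (r = 0.764, rho = 0.753, permutation p = 9e-05 and 0.00022, adjusted p = 0.00018 and 0.00044, r = 0.776 without the 2 farthest arrays). A larger share of slow muscle could account for it as well, with -0.0539 ± 0.227 given the slow fibre mean, r = -0.551 and rho = -0.472 (permutation p = 0.0177 and 0.0399, adjusted p = 0.0236 and 0.0533), and r = -0.347 without the 2 farthest arrays. Both covariates differ between the diets, which widens these errors. At day 3 the glucocorticoid target mean was at least 8.10 on low fat and at most 7.78 on high fat. The slow fibre mean was at most 7.94 on low fat and at least 8.78 on high fat. With no overlap, the differences given a covariate are extrapolated to levels that the diets did not share. The tests therefore do not choose between the 2 and establish neither.

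Of 100 splits of the arrays, the real one included, 1 gave as many genes as the real day 3 split (861, highest other 161). The same share held at day 28 (726, highest other 1), for the interaction (80, highest other 4) and with time on high fat (32, highest other 1). A share of 1 in 100 is the smallest these splits can give, so chance is an unlikely source of these counts but is not excluded. Without 1 array the interaction count still fell to as few as 19, and that of time on high fat to 3. With time on low fat 2 of 100 gave as many (20, highest other 41), and although that share is under 0.05, 15 of the other splits called genes and the real count was 0 in limma with only the arrays compared (862 at an unadjusted p under 0.05), so that count carries little weight. For the lists the share was under 0.05 at day 3 (2 of 100 splits, 17 lists, highest other 17) and day 28 (4 of 100, 15 lists, highest other 16). Yet at both days another split called at least as many lists, and the median of the other splits was 8 and 6 lists. The list counts at day 3 and day 28 therefore carry little weight as well. Chance cannot be excluded for the lists of the interaction (23 of 100, 8 lists, highest other 14) and of time on low fat (22 of 100, 10 lists, highest other 14) and high fat (35 of 100, 6 lists, highest other 11). The correlation of the fold changes between the days was reached by 2 of 100 splits (0.646, highest other 0.648).

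Each list mean and named gene was tested for an outlying array in each group of 6 arrays, 476 tests in all. In 50 of them, 17 of list means and 33 of named genes, 1 array stood apart, and high fat day 3 replicate 5 was that array in 17. Independent tests would give 23.8 at 1 in 20, but these tests share arrays and genes, so the excess is no measure against chance. The gap to the nearest array as a share of the range is given for each. In high fat day 3, replicate 5 was highest for the list means of fatty acid and triglyceride synthesis (0.694), cholesterol synthesis (0.721), interferon response (0.739), antigen presentation (0.670) and adipocyte markers (0.630), and lowest for fibroblast and tendon markers (0.713). Replicate 5 was also highest for Arxes2 (0.792), Cidea (0.666), Slc25a1 (0.851), Thrsp (0.725), Acly (0.798), H2-D1 (0.649), B2m (0.772) and Tspo (0.699), and lowest for Fbxo32 (0.737), Slc2a4 (0.627) and Nmrk2 (0.729). Other arrays of high fat day 3 were lowest for Egfl7 (0.682), Slc43a1 (0.693) and Snhg8 (0.681) and highest for Dnajb1 (0.739) and Rora (0.641).

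In high fat day 28, an array stood apart for the list means of mitochondrial biogenesis regulators (0.789, lowest), interferon response (0.634, highest), myogenesis (0.636, lowest) and macrophage markers (0.782, highest). The named genes there were Cdo1 (0.672), Scd1 (0.639), C1qb (0.662), B2m (0.659), Actc1 (0.642) and Hoxd8 (0.699), each with a high array, and Cebpd (0.655), Ndufb3 (0.683) and Mybph (0.702), each with a low one. In low fat day 28, these were the list means of fatty acid oxidation (0.836), heat shock (0.660), antigen presentation (0.643), angiogenesis (0.648) and ribosomal proteins (0.643), each with a high array, and oxidative phosphorylation (0.691), with a low one. Among its named genes Glul (0.639), Ech1 (0.657) and Ecrg4 (0.757) had a high array, and Tnmd (0.633) and Kera (0.720) a low one. In low fat day 3, insulin signalling (0.661) and Hoxd10 (0.675) had a high array, and Cdo1 (0.657) and Actc1 (0.643) a low one.

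The diet effect differed between the days for 16 named genes by the interaction test of limma. Of these, 11 were named because that same test called them, so the count is no separate result. Among the 11, 9 lost their call without at least 1 array and 10 in at least 1 other planned setting. The diet effect was higher at day 28 than at day 3 for Klf15 (0.88), Slc43a1 (1.64), Pik3ip1 (1.26), Ier3 (1.25), Asb15 (1.13), Ccrl2 (1.04) and Tcp11l2 (0.71), and lower for Casp8 (-1.76), Csad (-1.67), Gpx8 (-1.51), Tspo (-1.44), Pon3 (-1.36), Sparc (-0.81), Rgcc (-0.75), Ebp (-1.18) and Serpinh1 (-0.80).

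Of 527 probe sets without a gene of their own that passed the filter on dim genes, which the comparisons did not use, limma called 85 at day 3 (47 higher, 38 lower) and 86 at day 28 (30 higher, 56 lower). The pyruvate carboxylase control probe set was lower on high fat at both days, by -1.18 ± 0.312 at day 3 and -1.87 ± 0.312 at day 28 (log2, SE, two-sided exact permutation p = 0.0238 and 0.00216). It followed the adipocyte marker mean within groups with r = 0.897.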

How the results depend on the processing

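The covariates for the adipocyte and slow fibre means and the fits without the 4 arrays of high beta-actin ratio or the high fat day 3 array of highest adipocyte mean were chosen after seeing the data, and the others before. The cause of a change was not tested, save that a stricter threshold calls fewer genes by construction and that fits of fewer arrays have fewer degrees of freedom. The day 3 count of 861 genes became 507 with only the arrays compared, 18 with the slow fibre covariate and 383 at an adjusted p under 0.01. The day 28 count of 726 became 403 without the 4 arrays, 35 with the adipocyte and 27 with the slow fibre covariate, and 377 at the stricter threshold. The interaction count of 80 became 6 with no filter, 278 with array weights, 123 with the RNA quality covariate, 176 with the replicate block, 0 in limma with the adipocyte covariate (574 at an unadjusted p under 0.05) and 5 at the stricter threshold. The low fat time count of 20 became 3 with no filter, 40 with quantile normalization, 6 with the median shift, 132 with array weights, 32 with the replicate block, 2 without the 4 arrays and 34 with the slow fibre covariate. It was 0 in limma with only the arrays compared, with the adipocyte covariate and at the stricter threshold (862, 584 and 964 at an unadjusted p under 0.05). The high fat time count of 32 became 9 with no filter, 106 with array weights, 18 with each of the RNA quality, adipocyte and slow fibre covariates, and 2 at the stricter threshold. Leaving out 1 array gave 678 to 883 genes at day 3, 593 to 804 at day 28, 19 to 115 for the interaction, 0 to 59 and 3 to 51 with time on low and high fat (for the 0, limma had 847, 905 and 709 genes at an unadjusted p under 0.05), and a correlation of fold changes of 0.587 to 0.732, with a jackknife SE of 0.140. The correlation stayed within 0.535 to 0.702 in the other settings tried.

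The list counts of 17, 15, 8, 10 and 6 became 0 in each comparison by camera with an estimated correlation (9, 7, 1, 1 and 2 at an unadjusted p under 0.05). With the slow fibre covariate there were 11 at day 3 and 5 at day 28, and by fry 1 for the interaction and 0 with time on either diet (6 and 4 at an unadjusted p under 0.05). With the slow fibre covariate the direction turned for the tricarboxylic acid cycle (-0.0162) and macrophage markers (0.58) at day 3 and protein breakdown (0.10) at day 28, for Myh7 (-0.60), Myl3 (-0.93), Myl2 (-0.44) and Angptl4 (0.97) at day 3, and for Myh7 (-0.38), Myl3 (-0.72), Myl2 (-0.22), Pdk4 (0.21), Ucp3 (0.15) and Fbxo32 (0.31) at day 28. The slow fibre genes are part of that covariate. With the adipocyte covariate it turned for cholesterol synthesis (median -0.10, with the test upward), interferon response (0.13) and antigen presentation (median -0.13, with the test upward) at day 28, adipocyte markers with time on low fat (-0.0381), Angptl4 (0.42) and Scd1 (0.0028) at day 3, and H2-D1 (0.11), B2m (0.0883), Angptl4 (0.42) and Ppargc1a (-0.0111) at day 28. The adipocyte markers make up that covariate. At day 28 Myh4 was -0.0250 with quantile normalization, and Fbxo32 was 0.0084 with array weights, 0.11 without low fat day 28 replicate 1 and 0.07 without replicate 6. All 41 genes called and named at day 3 kept their call without any 1 array and 31 in each other planned setting, and at day 28 these were 36 and 39 of 39. For the interaction these were 2 and 1 of 11, with time on low fat 0 and 0 of 10, and with time on high fat 1 and 5 of 11. The replicate numbers name different mice and were not taken as pairs. In 6 of 24 pairs of same-numbered arrays from 2 groups the first array matched its partner best among the 6 arrays of the other group. Chance alone would give 1 in 6, and the correlations of the pairs ran from -0.384 to 0.537, so this check neither shows nor excludes a pairing. Mean low fat levels of Tnni1 (3.15 and 3.34) lie near the array medians of 2.71 to 2.79, so the size of such folds depends on the background correction.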

Other observations

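Lists with no call by camera at either day held single genes that changed. Some of these lists were called by fry, angiogenesis upward at both days (adjusted p = 0.0216 and 0.0487). At day 3 fry also called insulin signalling downward (adjusted p = 0.00892) and the regulators of mitochondrial biogenesis upward (adjusted p = 0.0209). Of 14 angiogenesis genes, 4 rose and 1 fell at day 3, Kdr, a receptor of vascular endothelial growth factor, by 0.71 and Fgf1 by 0.87 among them, with a median log2 change of 0.20 and adjusted p = 0.0560 by camera, and 1 rose at day 28, Fgf1 (1.05), with a median of 0.16 and adjusted p = 0.0881. Of 24 genes of glycolysis, glycogen and glucose uptake, 2 rose and 3 fell at day 3 (median -0.09, adjusted p = 0.190), and 2 rose and 1 fell at day 28 (median 0.04, adjusted p = 0.359). Ldhb, the lactate dehydrogenase subunit of oxidative tissue, rose by 1.35 and 1.22, and the glucose transporter Slc2a1 by 0.69 and 0.44. Of 14 regulators of mitochondrial biogenesis, 2 rose and 1 fell at each day (medians 0.14 and 0.07, adjusted p = 0.0913 and 0.470), with Esrrg, a nuclear receptor, at 0.88 and 0.80. Of 19 insulin signalling genes, 1 rose and 3 fell at day 3 (median -0.17, adjusted p = 0.0694), and 1 rose and 1 fell at day 28 (median -0.05, adjusted p = 0.848).

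Of 12 myogenesis genes, 2 rose and 1 fell at each day, Chrna1, a subunit of the muscle acetylcholine receptor, by 0.78 at both, with medians of -0.02 and 0.08, adjusted p = 0.720 and 0.706, means of 0.13 and -0.05 and upward tests at both days. Of 5 inflammatory mediators, Cxcl12 rose at both days (0.59 and 0.42) and the chemokine Ccl8 fell at day 28 (-3.85), with medians of -0.24 and -0.18, adjusted p = 0.789 and 0.706, and an upward test at day 3. Of 20 heat shock and unfolded protein genes, 1 rose at day 3, Ddit3 (0.91), and 2 rose and 2 fell at day 28, Dnajb1 (1.78) among them, with medians of -0.05 and -0.11, means of -0.03 and 0.03, downward tests at both days and adjusted p = 0.957 and 0.154.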
